A study of Caenorhabditis elegans with 2 samples.

How the data were processed

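Binding of the zinc finger protein encoded by Y95B8A.8, also named zfr-1, was measured by chromatin immunoprecipitation and sequencing in whole Caenorhabditis elegans young adults. Per the labels, the animals carried a CRISPR insertion that fuses the protein to a TY1, EGFP and 3xFLAG tag at its own gene, were synchronised as starved larvae and were taken at 63 hours. Chromatin was sonicated to fragments of 200 to 800 bp and precipitated with an antibody against GFP. There was 1 group with 2 samples, which the labels call biological replicates 1 and 2. No second group was present, so the comparisons were between the replicates, and between the sites and chance placement, other genes or flanking sequence.

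The deposited files were peak lists on assembly ce11, per the file headers. For each replicate and for both replicates together there was a ranked list and a thresholded list. For both replicates together there was also a thresholded list called conservative. A further ranked list was paired with the conservative list because it alone held all of its peaks. Each list gives a position, a summit, a signal and a score per peak. The signal is the value of the authors' peak caller, is never negative, and was used here only to rank and describe peaks within 1 list or to correlate the same sites between the replicates. The score in the deposited lists follows from the irreproducible discovery rate (IDR), a measure of how well the ranks of a peak agree between repeated calls, and runs up to 1000. The deposited ranked lists also give the −log10 of that rate, from which the score was found to follow, with a score of 830 at a rate of 0.01. Every peak of each thresholded list was found in the ranked list of the same kind with a score of at least 830. In the opposite direction, 73 of the 1767 ranked peaks with that score were not in the thresholded list of both replicates. Per the file headers, the thresholded lists also derive from 1 further file, whose nature is not given in the sources used here, and from a control alignment. The aligner, the peak caller and their versions are not given in the sources used here. Sequencing depth is unknown, since peak lists hold no read totals, so no interval for a signal was computed. Signal tracks, the control library and the immunoprecipitation of untagged animals were not analysed here.

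The thresholded list of both replicates, with 1694 peaks, was the main list. Ensembl annotation release 115 on assembly WBcel235 was used, whose chromosome names and lengths were checked against the coordinates in the lists. Gene symbols were taken from RefSeq by WormBase identifier, which matched 19965 of the 19973 protein-coding genes. The 6 nuclear chromosomes were used. A peak was assigned to the protein-coding gene with the nearest annotated 5′ end within 1000 bp of the summit. Each summit was placed in 1 of 7 feature classes, in the order promoter (1000 bp upstream to 500 bp downstream of a protein-coding 5′ end), 5′ UTR, 3′ UTR, coding exon, intron, other gene and intergenic.

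The overlap of the replicates (at least 1 bp), the promoter share, the feature classes and the non-coding gene classes (summit within 250 bp) were set against 1000 random placements of the same peaks on their own chromosomes. The resulting p-values are two-sided, and the smallest that these placements can give is 0.001 before adjustment. X and the autosomes were compared with a two-sided exact binomial test against the X share of the genome length, and chromosome centres with the same test against 50%. For each of 29 gene lists, the share of genes with an assigned peak was compared with that of all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists. The lists were made from gene names, and some hold genes outside their title, for example unc-40 among the homeobox genes. Words of 6 bases, each taken with its reverse complement, were counted within 50 bp of the summit and in a window of equal width centred 250 bp to 1 side of the same peak. An exact McNemar test with Benjamini-Hochberg adjustment was run on peaks of odd rank and again on peaks of even rank, and a word was called only when both passed in the same direction. The threshold was an adjusted p of 0.05 throughout. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting error only. The p-values are over sites or genes, which are not replicates and not independent, since neighbouring genes can share a promoter or an operon. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

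The groups, the tests, the gene lists, the first set of alternative settings and the rule for naming genes were fixed before the data were examined. By that rule the text names the tagged gene, the genes assigned to the 20 peaks with the highest signal (a peak without such a gene is given by position), the 4 members with the highest signal of each gene list that passed, up to 2 of each list that did not, and the 2 genes at the highest signals of each non-coding class that passed. The genes rpl-18A and unc-44 in the report, and other genes named in the closing part, were chosen after their values were seen. Where few members carried a peak, fewer are named. The sperm genes with a peak are given as a count, and their names are not reported here.

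The steps were tested on simulated data. For the gene lists, over 19973 genes and 1694 peaks, 100 of 100 lists with a planted share of 40% were recovered and 0 of 100 random lists were called. For the sequence words, 19 of 20 words planted in 8% of the sites were recovered, and 0 of 2080 words were called in unchanged sites. The unchanged sites were random positions in the genome, so a difference in base composition between summit and flank was not simulated. Planted shares below 40% for the lists and below 8% for the words were not simulated either. For the non-coding classes, sites were planted at tRNA genes only, and that class was recovered in 10 of 10 rounds. Recovery of the other non-coding classes was not simulated. Over unchanged rounds, 0 of 100 tests of non-coding classes and 0 of 70 tests of feature classes were called.

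The alternative settings in that first set were the conservative list, the 847 peaks with the higher signal, the list of each replicate alone, promoter windows of 500 and 2000 bp, assignment to every 5′ end within 1000 bp, a background of genes with a ranked peak below the threshold, such peaks as the null in place of random placement, non-coding distances of 100 and 500 bp, summit matching within 50 bp, overlap of 50% of each peak, words of 8 bases, windows of 100 bp either side, and a flank centred 400 bp away. Alternatives added after seeing the data were merging of peaks within 300 bp, a minimum signal of 20, leaving out peaks near tRNA, snoRNA and snRNA genes, comparing the stronger 50% of a replicate's peaks with the whole other list, and sequence from weaker ranked peaks of equal base composition in place of the flank.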

Results

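The data were sites bound by the zinc finger protein of Y95B8A.8 (zfr-1, WBGene00022388), tagged with GFP at its own gene on chromosome I, in whole young adult worms at 63 hours. The 2 samples formed 1 group of biological replicates, per the labels. The list called on both replicates held 1694 peaks, with a median signal of 78.6 (interquartile range 65.6 to 101) and a highest signal of 617. The conservative list held 1538 peaks, and the lists of replicate 1 and replicate 2 held 733 and 667. Of the 1694 peaks, 1587 had the same width of 290 bp. Sequencing depth is unknown, and coordinates are on assembly ce11.

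Of the 20 sites with the highest signal, 5 lay at ribosomal protein genes. The first was upstream of rpl-3, a protein of the large ribosomal subunit (III, 3867471 to 3867698, signal 617, summit 267 bp from the 5′ end). It was followed by the promoter of tasp-1 (III, 10759142 to 10759367, signal 502) and that of rpl-15 (IV, 654825 to 655019, signal 460). A site with signal 437 lay downstream of C46C2.7, 832 bp from its 5′ end. A site with signal 432 lay between the divergent genes Y17G9B.5 and rpl-18A (IV, 4749991 to 4750186). Further promoter sites were at rpl-35 (426), at cdc-48.1 (416), which encodes an AAA ATPase that unfolds ubiquitinated proteins, at mog-4 (387), an RNA helicase of the germ line sex decision, and at eel-1 (385), a ubiquitin ligase. The site assigned to rpa-2 (383), a subunit of the single-strand DNA binding complex of replication, lay 661 bp from its 5′ end, and kin-35, on the same part of chromosome I, had a site of its own (333). The remaining named genes among the first 20 were K08F11.1 (355), rps-24 (325), hcp-3 (315), which encodes the centromeric histone, mtcu-2 (308) and drr-2 (293). The other 4 of these 20 peaks had no protein-coding 5′ end within 1000 bp. They lay beside the pseudogene K08F11.6 (IV, 4727958 to 4728135, signal 373), in an intergenic part of X (1375137 to 1375426, signal 305), in an intron of pxn-1 next to the snoRNA gene ZK994.7 (V, 8500463 to 8500649, signal 296) and beside the non-coding RNA gene tts-1 (X, 1503733 to 1504194, signal 293). All 20 of these peaks overlapped a thresholded peak of each replicate.

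The tagged gene itself, zfr-1 (I, 853451 to 872827, plus strand), had 1 peak within 2000 bp, at 852050 to 852339 with its summit at 852195, upstream of the annotated gene. Its signal was 86.6, at rank 664 of 1694. The thresholded lists of the single replicates held 0 peaks there. The ranked lists held weaker ones, with scores of 607 in replicate 1 and 724 in replicate 2, both under the threshold of 830.

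The first comparison was between the replicates. Of the 733 peaks of replicate 1, 403 overlapped a peak of replicate 2 (55.0%, 51.3 to 58.6), and 401 of the 667 peaks of replicate 2 overlapped 1 of replicate 1 (60.1%, 56.3 to 63.9). Random placement gave 0.389% and 0.414% (two-sided permutation p = 0.001 for each, the smallest that 1000 placements can give). The sites at rpl-3 and rpl-15 were in both lists, while that at pgl-3 was in replicate 2 alone and that at rpn-9, a proteasome subunit gene, in replicate 1 alone. Most peaks of each replicate were also in the list of both replicates, 93.2% and 93.4%. The reverse did not hold: of the 1694 peaks called on both replicates, 396 (23.4%) overlapped a thresholded peak of each replicate. A further 776 (45.8%) overlapped a thresholded peak of neither replicate. Across the 1508 sites with a summit within 100 bp in both ranked lists, the signals had a Spearman correlation of 0.432 and, on the log2 scale, a Pearson correlation of 0.58. Sites are not independent replicates, so no p is given, and the matched sites were 89% of the 1694.

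**Figure D1:**
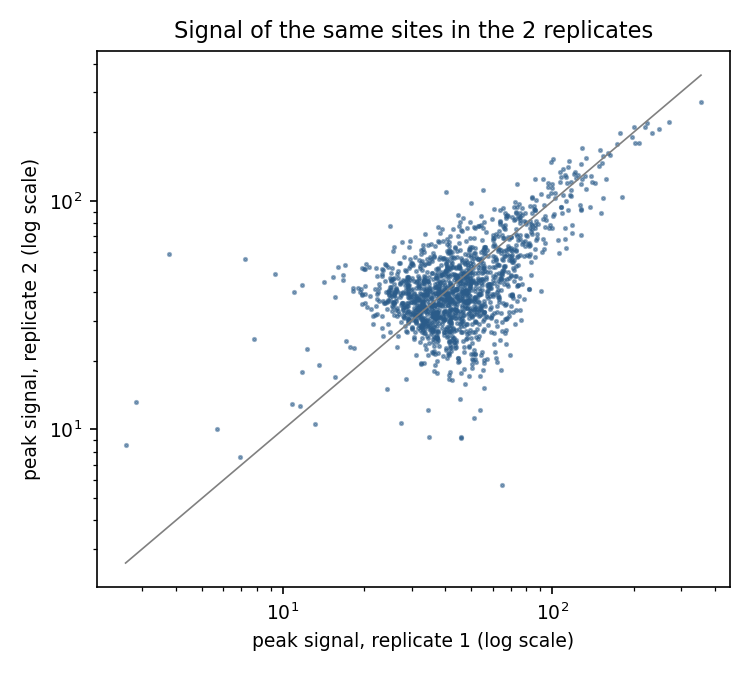
Peak signal of the same sites in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), in the peak caller's own units; each point is 1 of the 1508 matched sites and the line marks equal signal. The strongest sites lie along the line, and the Spearman correlation is 0.432.

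The second comparison asked where in the genome the sites lie. Sites concentrated at promoters: 1061 of 1694 summits (62.6%, 60.3 to 64.9) lay within 1000 bp of a protein-coding 5′ end, against 41.1% of randomly placed summits (1.53-fold, two-sided permutation p = 0.001, the smallest possible). These peaks were assigned to 950 genes, 4.76% of the 19973 annotated, and 748 of them lay at or upstream of the 5′ end, with a median position of -152 bp. For 382 of the peaks at least 1 further gene also had a 5′ end within 1000 bp, as at Y17G9B.5 and rpl-18A. Promoters held 952 summits (1.77-fold over random placement) and 3′ UTRs held 101 (2.43-fold). Coding exons held 93 (0.332-fold), introns 209 (0.488-fold) and intergenic sequence 267 (0.769-fold), and each of these 5 classes had a permutation p of 0.001, the smallest possible (adjusted p = 0.0014). The 67 summits in other genes (1.22-fold, adjusted p = 0.111) and the 5 in 5′ UTRs (1.22-fold, adjusted p = 0.791) did not pass the permutation test. When ranked peaks below the threshold replaced random placement, the lower share of intergenic sites was no longer called (0.955-fold, adjusted exact p = 0.499, against 0.0014 to 0.499 over 8 alternatives). Annotated 5′ ends are not always true starts in this species, where many transcripts are trans-spliced, and random placement takes no account of open chromatin.

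**Figure D2:**
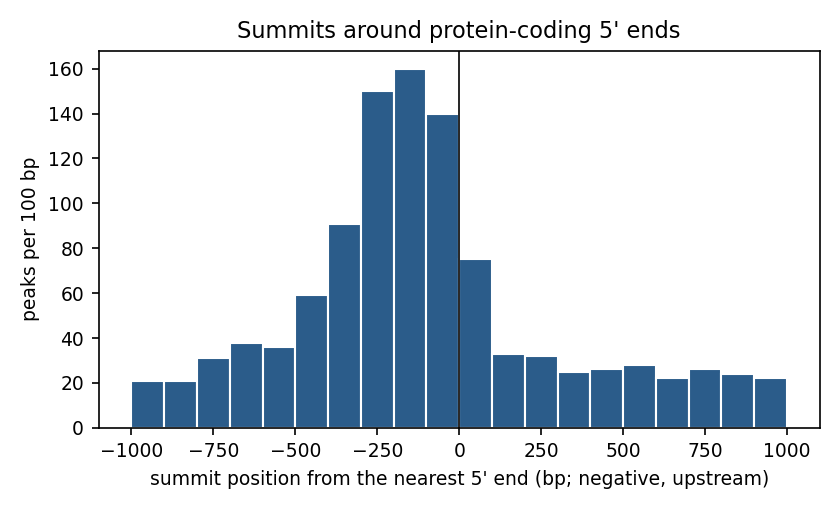
Number of peaks per 100 bp (y axis) by the position of the summit from the nearest protein-coding 5′ end (x axis, bp, negative upstream), for the 1061 assigned peaks. The highest bar, 160 peaks, lies from 200 to 100 bp upstream.

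The X chromosome held fewer peaks per megabase than the autosomes. It held 158 of the 1694 peaks (9.33%, 7.98 to 10.8), while it makes up 17.7% of the genome. Its density was 8.92 peaks per megabase against 18.6 on the autosomes (ratio 0.479, two-sided exact binomial p = 3.47e-22), and with the list of replicate 2 alone the ratio was lower, 0.289. In a split made after the result was seen, the ratio was 0.274 for the 1061 peaks assigned to a protein-coding gene (two-sided exact binomial p = 1.19e-31). For the 633 peaks not assigned it was 0.864 and did not pass (two-sided exact binomial p = 0.193), and the difference between these 2 ratios was not tested. The 126 peaks near tRNA genes were denser on X per megabase (ratio 2.59, two-sided exact binomial p = 1.62e-06), where 276 of the 612 tRNA genes lie. That test takes no account of the number of tRNA genes. Per gene the direction was the opposite, with a peak at 51 of 276 tRNA genes on X and at 89 of 336 on the autosomes (ratio 0.698). Chromosomes I and III had the highest densities, 23 and 24.8 peaks per megabase, followed by II (17.9), IV (17.1) and V (13.1). Protein-coding genes on X with an assigned peak included hsp-3, nhr-48, mdl-1 and ajm-1. Along the autosomes, 943 of 1536 summits (61.4%, 58.9 to 63.8) lay in the middle 50% of their chromosome (two-sided exact binomial p = 3.77e-19 against 50%), where gene density is higher in this species. The tests on X and on the centres assume that sites fall independently.

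**Figure D3:**
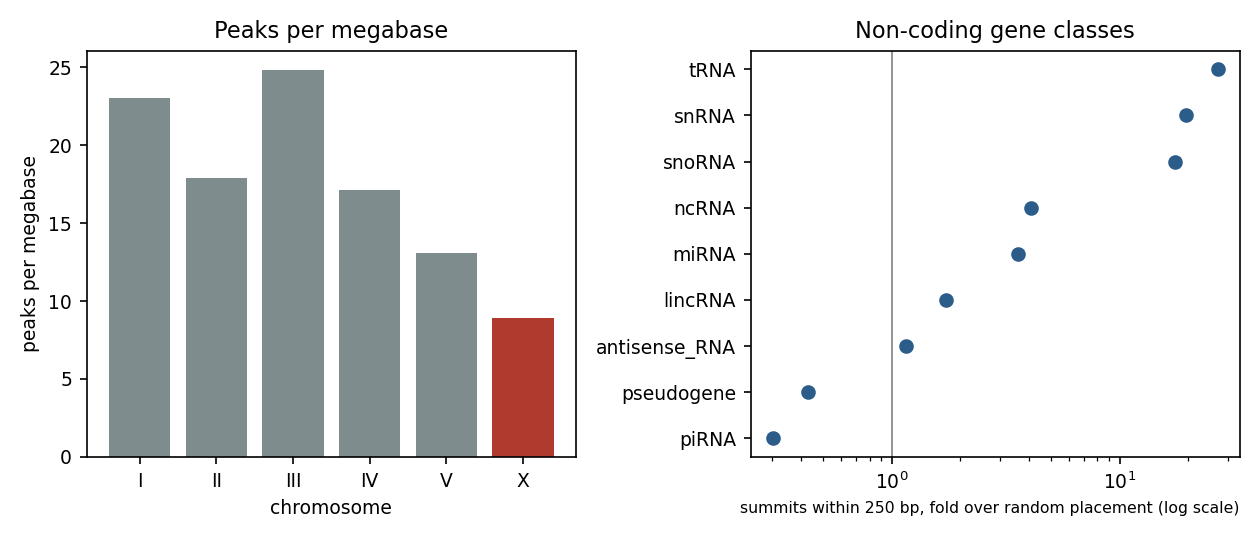
Left, peaks per megabase (y axis) on each chromosome (x axis), with X, the lowest at 8.92, in red. Right, number of summits within 250 bp of genes of each non-coding class as a fold over random placement (x axis, log scale; the line marks equality), highest for tRNA genes at 26.9; rRNA genes, with 0 summits, are not drawn.

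The third comparison asked which groups of protein-coding genes carry sites. Ribosomal protein genes stood first: 34 of 81 had an assigned peak (42%, 31.1 to 53.5), against 4.60% of all other genes (9.12-fold, adjusted exact p = 1.55e-22, two-sided Fisher's test as for each list), led by rpl-3, rpl-15, rpl-35 and rps-24. Translation factor genes followed the same direction with 10 of 39 (25.6%, 5.44-fold, adjusted exact p = 7.39e-05). Their strongest members were eef-2, the elongation factor of ribosome translocation (158), iff-2 (154), the initiation factor subunit eif-3.C and eef-1G (113). Of the genes for the mitochondrial respiratory chain and ATP synthase, 8 of 40 had a peak (20%, 4.23-fold, adjusted exact p = 0.00208), among them the cytochrome oxidase subunits cox-5A (260), cox-5B (218) and cox-6A (145) and the ATP synthase subunit atp-1 (158). The summit assigned to cox-6A lay 857 bp from its 5′ end and inside the snRNA gene F54D8.7, so this peak counts for both groups, and without the peaks near tRNA, snoRNA and snRNA genes the list stood at 4.08-fold (adjusted exact p = 0.00608). Genes of the mitochondrial ribosome did not differ from other genes in this test, with 3 of 67, among them mrpl-15 and mrpl-23 (0.941-fold, 95% interval of the share 0.933% to 12.5%). The control library and untagged animals were not analysed here, so the shares of these and the other lists could not be set against the background at highly transcribed genes.

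Genes with germ line and cell cycle functions also carried peaks more often than other genes. Of the germ line markers, 22 of 61 had a peak (36.1%, 24.2 to 49.4, 7.74-fold, adjusted exact p = 3.43e-13). These included cpg-1, an eggshell proteoglycan (269), egg-1, a receptor needed for fertilisation (157), pgl-3, a P granule component (143), and mex-1, an RNA-binding protein of the early embryo (141). Of the DNA replication and cell cycle genes, 23 of 97 had a peak (23.7%, 15.7 to 33.4, 5.08-fold, adjusted exact p = 1.10e-09), led by cdc-48.1, rpa-2, hcp-3 and the kinetochore gene hcp-4 (251). Of the histone genes, 14 of 81 had a peak (17.3%, 3.67-fold, adjusted exact p = 1.49e-04), among them his-68 (154), his-60 (113), his-57 (113) and the linker histone hil-4 (100.4). Most of these 14 summits lay downstream of the assigned 5′ end, as at his-60 (230 bp), his-57 (534 bp) and hil-4 (59 bp), while that of his-68 lay 158 bp upstream. Whether reads were shared between copies of histone genes was not tested. Small RNA pathway genes had a peak in 10 of 88 cases (11.4%, 2.40-fold, adjusted exact p = 0.0286). Their strongest members were snpc-3.4 (182), which belongs to a complex of snRNA and piRNA gene transcription, and pgl-3, glh-2 (130) and pid-5 (128); 8 genes of this list are also on the germ line list. The animals were taken whole, so these shares do not show in which tissue a site was bound.

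The other 3 lists on the higher side passed narrowly, each with an adjusted exact p of 0.0449. They were the proteasome subunits with 5 of 33 (3.20-fold), including rpn-9 (102), rpn-3 (100.4), rpn-11 (95.5) and pbs-5 (57.8), and the heat shock and chaperone genes with 8 of 70 (2.41-fold), including dnj-28 (197), dnj-13 (181), hsp-1 (164) and hsp-3 (120.1). The last was a list of RNA decay and translation control genes with 4 of 22 (3.83-fold), namely the exonuclease gene xrn-2 (136) and the CCR4-NOT subunit genes ntl-2.1 (93.3), ntl-3 (69.6) and let-711 (52.7). In 3 lists, genes carried peaks less often than other genes. Of the C-type lectins and lysozymes 4 of 343 had a peak (0.242-fold, adjusted exact p = 0.00208), which were clec-57 (115), clec-87 (73.5), clec-126 (63.4) and clec-111 (62.2). The peaks at clec-57 and clec-126 also lay within 250 bp of a snRNA gene (F08H9.11) and a tRNA gene, and without the peaks near such genes the list stood at 0.133-fold (adjusted exact p = 3.44e-04). Of the detoxification enzymes 2 of 210 had 1, the peroxiredoxin gene prdx-2 (90.6) and ugt-40 (66.7), the latter also near a snRNA gene (0.199-fold, adjusted exact p = 0.0175). Of the nuclear hormone receptor genes 5 of 269 had 1 (0.388-fold, adjusted exact p = 0.0449), among them nhr-48 (81.4), nhr-41 (81.0, also near a tRNA gene), nhr-105 (79.0) and nhr-47 (68.2).

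Of these 13 lists, 6 passed under each of 11 alternatives: ribosomal proteins, translation factors, the respiratory chain, DNA replication and cell cycle, germ line markers, and C-type lectins and lysozymes. Without replicate 1, that is with the list of replicate 2 alone, germ line markers stood at 11.7-fold, translation factors at 8.42-fold and C-type lectins at 0.133-fold. The respiratory chain stood at 7.02-fold without replicate 1 and 8.23-fold without replicate 2, and C-type lectins had 0 peaks without replicate 2. The call for histone genes was lost without replicate 2 (1.72-fold, adjusted exact p = 0.405, against 6.43e-09 to 0.405 over the alternatives). The calls for the other 6 lists were each lost under at least 3 alternatives. Over the 11 alternatives, lost calls or not, the fold ranged from 1.41 to 4.23 for proteasome genes (adjusted exact p from 0.00791 to 0.709), from 2.03 to 4.25 for chaperone genes (3.32e-07 to 0.132), from 1.57 to 3.72 for small RNA genes (5.97e-04 to 0.393) and from 2.10 to 4.95 for RNA decay genes (0.0012 to 0.528). It ranged from 0 to 0.509 for nuclear hormone receptors (adjusted exact p from 0.0021 to 0.276) and from 0 to 0.434 for detoxification enzymes (0.00227 to 0.276), so each of the 6 stayed on the same side of 1.

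The other 16 lists did not pass. Nuclear pore genes had a peak in 4 of 26 cases (adjusted exact p = 0.0684), including npp-8 and npp-3, tubulins and actins in 3 of 18 (adjusted exact p = 0.0993), including act-2 and tba-2, and the vacuolar ATPase in 3 of 20 (adjusted exact p = 0.121), including vha-2 and vha-11. Chromatin regulators had a peak in 10 cases (8.4% of the list, adjusted exact p = 0.126), led by ash-2 (232) and cbp-1 (192), autophagy and lysosome genes in 7 of 99 (adjusted exact p = 0.365), including lgg-2 and lgg-1, and splicing genes in 4 of 47 (adjusted exact p = 0.413), including rsp-2 and rsp-8. Collagen genes had a peak in 3 of 176 cases (0.356-fold, adjusted exact p = 0.121), including col-63 and col-85. Homeobox genes had a peak in 3 of 105 cases (adjusted exact p = 0.570), of which unc-42 encodes a homeodomain protein and unc-40 and unc-44 do not, and bHLH genes in 1 of 38, mdl-1. Among the markers of single tissues, 3 of 38 intestinal genes (including fat-6 and asp-1), 3 of 44 neuronal genes (including mec-17 and nlp-12), 1 of 30 hypodermal genes (ajm-1) and 2 of 98 sperm genes had a peak. No body muscle marker (0 of 36, which allows a share of up to 9.74%) and no pharynx marker (0 of 28, up to 12.3%) had 1. The intervals of these 6 marker lists include the 4.76% of all genes, so no difference was detected. Of the 16 lists, 6 passed under at least 1 of the 11 alternatives. Nuclear pore genes passed under 4 (2.58-fold to 5.38-fold over the alternatives, adjusted exact p from 0.00227 to 0.121), tubulins and actins under 3 (2.55-fold to 7.77-fold, 0.0085 to 0.297) and chromatin regulators under 3 (1.68-fold to 2.75-fold, 0.00412 to 0.257), in part with the list of 1 replicate alone. Collagen genes passed on the lower side under 2 (0.130-fold to 0.628-fold, adjusted exact p from 0.0225 to 0.751), and splicing genes and the vacuolar ATPase passed only with assignment to every 5′ end.

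**Figure D4:**
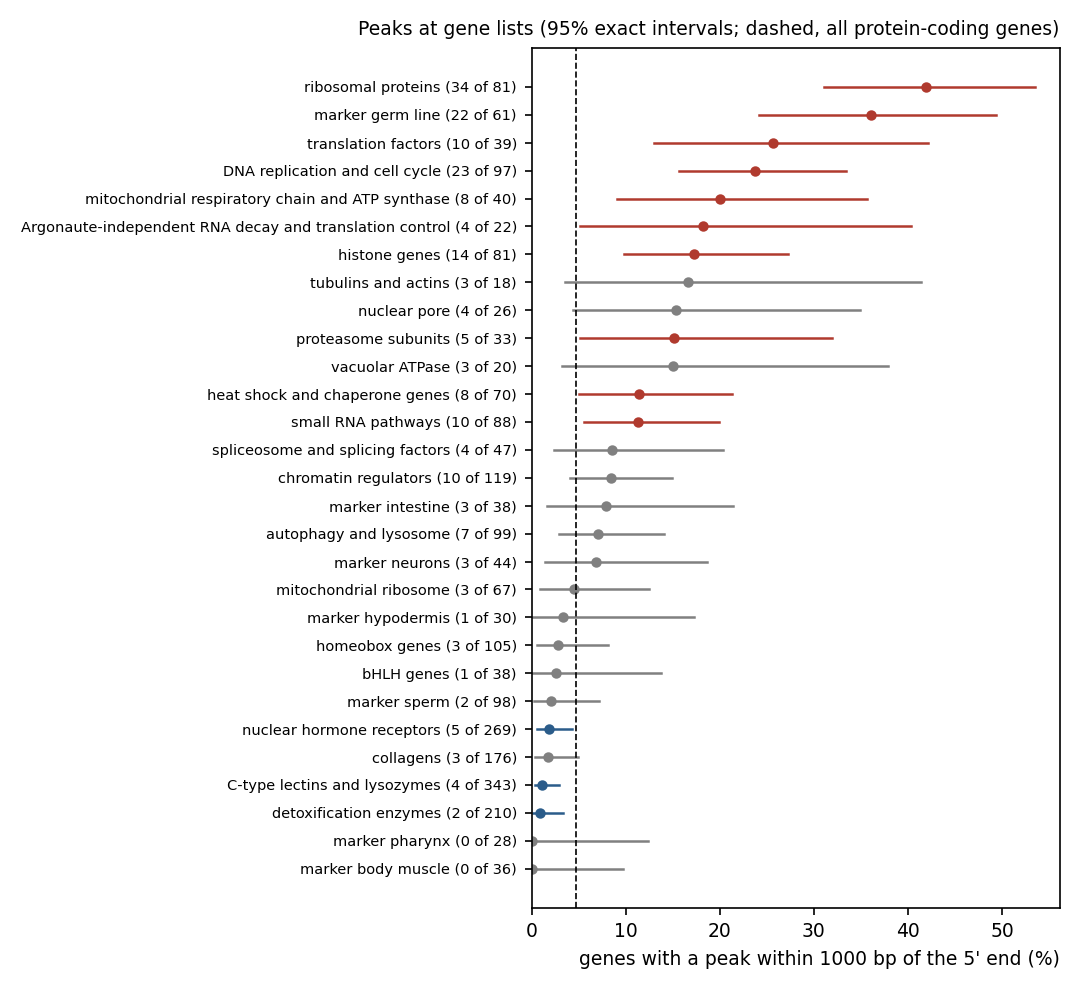
Share of the genes of each list with a peak within 1000 bp of the 5′ end (x axis, percent; points, with exact 95% intervals as lines); the dashed line marks the 4.76% of all protein-coding genes. Lists that passed are red (higher) or blue (lower), with ribosomal proteins first at 42%, and the others are grey.

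The fourth comparison was with genes that are not protein-coding. Summits were found near tRNA, snRNA and snoRNA genes far more often than by random placement. Of the summits, 126 lay within 250 bp of a tRNA gene against 4.68 at random (26.9-fold), with the strongest at F15G9.t1 (X, signal 154) and M02F4.t1 (X, signal 140.2). There were 26 summits at snRNA genes (19.5-fold), the strongest at sls-2.1 (II, 5844865 to 5844974, signal 255.6) and sls-2.8 (229), which encode the SL2 leader RNA used in trans-splicing. There were 70 at snoRNA genes (17.5-fold), the strongest at ZK994.7 (296) and F59C6.15 (266). Genes annotated as ncRNA had 253 summits (4.09-fold), the strongest at K08F11.7 and tts-1. Pseudogenes had 29 (0.427-fold), the strongest at K08F11.6 and T08G5.13, and piRNA genes had 19 (0.301-fold), the strongest at 21ur-13751 and 21ur-12279. Each of these 6 classes had a permutation p of 0.001, the smallest possible (adjusted p = 0.00167). With the list of replicate 2 alone the fold at tRNA genes was 15.8 and that at piRNA genes 0.572 by the same placement. miRNA genes had 8 summits (3.58-fold, adjusted permutation p = 0.00428), the strongest at mir-4932 and mir-35. lincRNA genes (10 summits, 1.74-fold, adjusted permutation p = 0.0987), antisense RNA genes (3 summits) and rRNA genes (0 summits against 0.318 at random) did not pass. The call for miRNA genes was lost without replicate 2 (2.06-fold, adjusted permutation p = 0.323, the highest of 10 alternatives, of which the lowest gave 0.00143), and that for piRNA genes when ranked peaks below the threshold replaced random placement (0.817-fold, adjusted exact p = 0.574, with 0.00143 as the lowest of 10 alternatives).

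The fifth comparison was of sequence at the summits with the flank of the same sites. Words rich in G and C, and in the dinucleotide CG, were found more often at the summits. Of 2080 words of 6 bases, 299 passed both at peaks of odd rank and at peaks of even rank, 191 more often at the summit and 108 more often in the flank. Of the 191, 159 had at least 4 G or C and 143 held a CG. GCGCGC was present at 144 summits and in 14 flanks (8.50% and 0.826% of the peaks), GCGCGA at 157 and in 20, and CGCGCG at 110 and in 14; these are the words with the highest ratios of summit to flank. The summit windows had a mean of 45.4% G and C (SD 9.45, n = 1694), the flanks 36.4% (SD 8.99, n = 1694). Against ranked peaks below the threshold with equal G and C content, 37 of the 191 words were called again (19.4%). The median ratio of the 191 words fell from 3.04 to 1.63 in that setting, which was added after the data were seen.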

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

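The sites below were looked at only after the results were seen. In the ranked list of both replicates, 73 sites passed the score of 830 and were not in the thresholded list, so the report's comparisons do not use them. The strongest lay on X at 15810950 to 15811164, with its summit at 15811107 in intergenic sequence and a signal of 1946.8, which is 3.15 times the highest signal in the thresholded list. It was the only 1 of the 73 above that signal, and its signal was 990.8 in replicate 1 and 1111.5 in replicate 2. The next were also intergenic and on X, with summits at 11785822 (signal 418) and 15808192 (signal 389). Of the 73 sites, 63 were intergenic (86.3%), 6 lay within 1000 bp of a protein-coding 5′ end, 13 lay on X, and 0 lay near a tRNA, snoRNA or snRNA gene. Their median signal was 110.5, against 78.6 in the thresholded list. No explanation for their absence from that list was tested.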

How the results depend on the processing

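The settings that merged peaks, set a minimum signal, left out peaks near tRNA, snoRNA and snRNA genes, compared stronger peaks with a whole other list, or used weaker peaks of equal base composition were chosen only after the results were seen. Under their alternatives the promoter share stayed above random placement (1.23-fold to 2.02-fold), X stayed below the autosomes (ratio 0.289 to 0.477), the share of autosomal summits in chromosome centres stayed at 61.1% to 62.1%, and the number of feature classes past the threshold stayed at 4 to 6 of 7. With the 847 peaks of higher signal, 7 gene lists and 146 words passed, and with the conservative list 8 gene lists passed, against 13 lists and 299 words in the main list. Assignment to every 5′ end within 1000 bp raised the number of lists to 19, and a minimum signal of 20 gave 302 words, the highest numbers over the alternatives. Without 1 replicate, the lists held 667 to 733 peaks, 7 to 12 gene lists and 87 to 89 words passed, and 0 peaks lay at the tagged gene in either list. Fewer peaks in these lists are part of their construction, and other causes were not tested. With overlap of 50% of each peak, 49.8% of the peaks of replicate 1 and 55.2% of those of replicate 2 were shared. The stronger 50% of each list shared 60.9% and 67.0%, and against the whole other list 76.2% and 78.7%. With summits matched within 50 bp the Spearman correlation was 0.488. With words of 8 bases 8 were called, with the flank centred 400 bp away 189, and against weaker peaks of equal base composition 50; the cause was not tested for the first pair. Leaving out the peaks near tRNA, snoRNA and snRNA genes gave 179 words and 4 non-coding classes. By its construction this setting gives 0 summits, a fold of 0, at tRNA, at snoRNA and at snRNA genes, and it turned the share in other genes from 1.22-fold to 0.695-fold (adjusted permutation p = 0.0408, against 0.0408 to 0.744 over 8 alternatives). Of the values for single classes and gene lists, 423 kept their side of the threshold, 32 were no longer past it and 16 newly passed it. The 423 include values past it in neither setting whose fold crossed 1. Genes of the mitochondrial ribosome are a case (0.941-fold, 0.401-fold to 1.66-fold over the alternatives). Another 4 reversed with the main or the alternative value past the threshold, all without the peaks near tRNA, snoRNA and snRNA genes. Depth is unknown, so its part in the number of sites could not be separated from that of the threshold. The labels give 1 group, so no comparison between groups was run.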

Other observations

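Chosen only after the results were seen were the tests on spliced leader genes, on tRNA isotypes, on sites below the threshold and on words of 8 bases against weaker peaks, the tests of the X chromosome against protein-coding, tRNA and snoRNA genes and its split by assigned peaks, and the test of the median word ratio without the non-coding sites. Genes of the SL2 leader RNA carried sites more often than the other snRNA genes. Of the 18 sls-2 genes 10 had a summit within 250 bp (55.6%, 30.8 to 78.5), against 16 of the 111 other snRNA genes (two-sided Fisher's exact p = 3.25e-04, 1 of 5 groups compared, unadjusted). None of the 12 sls-1 genes, which encode the SL1 leader RNA, had 1 (0 of 12, up to 26.5%); the sequence of each sls-1 gene occurs more than once in the genome, while that of each sls-2 gene occurs once. Both annotated sup genes on the snRNA list had a summit, with sup-6 at a signal of 213 (2 of 2, two-sided Fisher's exact p = 0.0394, unadjusted). Of the tRNA genes, 140 of 612 had a summit (22.9%, 19.6 to 26.4). Among isotypes with at least 10 genes, the share ran from 8 of 20 for asparagine and 15 of 41 for glutamate down to 0 of 14 for phenylalanine (up to 23.2%). Differences between the 20 isotypes with at least 10 genes did not pass a permutation test (p = 0.141).

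Ribosomal protein genes also came first among sites below the score threshold. The 1694 ranked peaks with the highest signal below the threshold were used. Their signals of 51.1 to 124 overlap those of the thresholded list, so they differ from it by score more than by signal. Among them, 17 of 81 ribosomal protein genes had an assigned peak (21%, 5.01-fold, adjusted p = 1.21e-06 by Fisher's exact test). Of the other lists, 4 passed on the higher side and 1 on the lower side, each with an adjusted p of 0.0271. The higher ones were intestinal markers with 6 of 38 (3.73-fold), splicing genes with 7 of 47 (3.52-fold), germ line markers with 8 of 61 (3.10-fold) and small RNA genes with 10 of 88 (2.69-fold), and the lower one was nuclear hormone receptors (0.259-fold). Intestinal markers and splicing genes did not pass in the thresholded list. Among the lists that did not pass at the sites below the threshold were proteasome genes (adjusted exact p = 0.0504) and DNA replication and cell cycle genes (0.072). The respiratory chain (0.0768), translation factors (0.41) and histone genes (0.903) did not pass there either. The difference between the sites above and below the threshold was not tested.

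Among words of 8 bases, GCGCGAAA was present within 50 bp of 54 summits and in 2 flanks. Its reverse complement TTTCGCGC is the textbook site of the cell cycle factor EFL-1 and its relatives. Examples lay at III 9617092 to 9617099 in the site assigned to hcp-3, the centromeric histone gene, and at III 1619081 to 1619088 near Y22D7AL.10. Another lay at IV 7796922 to 7796929 near sgo-1, which encodes shugoshin. Whether this word lies at cell cycle genes more often than at other genes was not tested. GTACGGTA was present at 38 summits and in 1 flank, with an example at I 3866605 to 3866612 in the site assigned to hcp-4. A further word, AGACGCAG, was present at 89 summits and in 14 flanks, with an example at III 13643713 to 13643720 in the site at drr-2. None of the 8 words called was near a tRNA gene at more than 3 of its sites. Against weaker peaks of equal G and C content none of the 8 was called in both sets of ranks. Each stayed 3.24 to 5.19 times as frequent at the summits, with GCGCGAAA at 54 against 10, GTACGGTA at 38 against 11 and AGACGCAG at 89 against 26. G and C content was equal by construction, so it is not the source of these ratios. Without a call in both sets of ranks the ratios are not established, and other features of base composition were not matched.

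The first pattern weighed was the low number of sites on X, with a ratio of 0.274 for peaks assigned to protein-coding genes and 0.864 for the others, which include 76 of the 126 peaks near tRNA genes. A lower number of genes on X could be part of the cause, since X had 0.738 times as many protein-coding genes per megabase as the autosomes. This is a count of all annotated genes, and its interval (0.709 to 0.768) assumes that genes fall independently. As the whole cause, fewer genes are argued against, since 54 of 2731 protein-coding genes on X had a peak (1.98%) against 896 of 17242 on the autosomes (5.20%). The ratio of these shares was 0.380 (0.289 to 0.485 by resampling blocks of 100 kb). Lower coverage or mapping on X could be part of the cause too, since tRNA genes on X had a peak less often than those on the autosomes. The counts were 51 of 276 against 89 of 336 (ratio 0.698, 0.476 to 0.979 by resampling blocks of 100 kb). The density of ranked peaks below the threshold on X was 0.859 times that of the autosomes. Chromosome IV had an equally low density of them (817 per megabase against 819 on X), so this value does not single out X. As the whole cause, lower coverage or mapping is argued against at tRNA genes, where the ratio was 1.83 times that at protein-coding genes (1.23 to 2.72 by the same resampling). It is not argued against at snoRNA genes, where 1 of 33 on X against 68 of 313 on the autosomes had a peak. The ratio there was 0.367 times that at protein-coding genes (0 to 1.42), so the 2 classes do not decide it together. Open and untested stay a difference in chromatin or in germ line expression between X and the autosomes and the signal of an untagged control, and no biological explanation was tested, since the design has 1 group.

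The next pattern was the sites at tRNA, snoRNA and snRNA genes, 222 of the 1694 peaks (13.1%). Reads shared between identical gene copies are argued against as the whole cause. At genes whose sequence occurs once in the genome the lowest fold of the 3 classes was 17.3, at snoRNA genes (adjusted permutation p = 0.00112). Of the snoRNA genes, 343 of 346 occur once, so the explanation bears mainly on the other classes. The fold at tRNA genes was 18.2 for the 140 that occur once and 30.5 for the other 472, so a part is left open there. At snRNA genes it was 24.0 and 12.1. Only exact full-length copies were counted, so reads shared between near-identical copies were not tested. Promoters of neighbouring protein-coding genes are argued against too, since among summits away from protein-coding 5′ ends the lowest fold was 27, again at snoRNA genes (adjusted permutation p = 0.00112). Open and untested stays the recovery of open, highly transcribed chromatin without binding of the tagged protein, which can enrich such genes in immunoprecipitations with many antibodies, because untagged animals and the control library were not analysed here; this applies equally to the ribosomal protein, translation factor and respiratory chain genes. No biological explanation was tested.

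The last pattern was the G and C rich words at the summits. Base composition may be part of the cause, and its part cannot be told apart from that of the words themselves. Against weaker peaks of equal G and C content 37 of the 191 words were called again (19.4%, 14 to 25.7). This lay between the bounds of 10% and 50% set beforehand, and the median ratio of the 191 words fell from 3.04 to 1.63. Words of the non-coding genes are argued against as the whole cause, since without the peaks near tRNA, snoRNA and snRNA genes the median ratio of the 191 words was 2.75 (interquartile range 2.14 to 3.47). The share called again in that setting, 53.9% (46.6 to 61.1), lay above the 50% set beforehand, but its interval includes 50%, so this value alone does not decide. Whether a word is bound by the protein was not tested.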
